A study of Xenopus laevis with 4 samples.

How the data were processed

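Expression was measured with Affymetrix arrays in explants of presumptive ectoderm (animal caps) of the frog Xenopus laevis. Per the labels' protocols, embryos received synthetic RNA at the 2-cell stage, the caps were cut at stage 9 to 10 and cultured in Danilchik's medium with 0.1% BSA, and total RNA was taken at the equivalent of stage 12. The labels name 3 injected RNAs. ICD was put on 2 arrays, DBM on 1 and HMM on 1, and 4 arrays were used in all. ICD is the usual name of the intracellular domain of Notch, which activates the pathway without ligand. DBM is the usual name of a form of the Notch effector rbpj, also called Su(H), that cannot bind DNA and blocks the pathway. HMM is not spelt out in the labels. The labels list no array of uninjected caps, no clutch and no batch, and nothing says whether the ICD arrays came from separate clutches. The limma p-values therefore measure only the spread between these arrays, which may be technical.

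The deposited values are MAS5 signals, an intensity on a linear scale with 1 value per probe set and array, per the submitters' processing notes, which give no version of MAS5. No detection call was used here, so a low signal carries no statement about presence. The table held 32635 probe sets, 96 of them controls, and all of its value columns were assigned to a sample. Gene names came from the platform annotation, updated by Entrez Gene identifier through the RefSeq gene table, in which 97.5% of the annotated identifiers were found and which changed 2 symbols. Of the non-control probe sets, 15495 had 1 symbol, 279 had several and were left unnamed, and 16765 had none and are unnamed here. The suffixes L and S mark the homeologous copies of a gene in this allotetraploid species, and copies were counted separately. MAS5 probe sets can cross-hybridize between homeologs and between members of the hes5 cluster, so single copies are named as the probe set's annotation gives them.

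The 2% trimmed mean signal was 150.7 on ICD replicate 1, 376.8 on ICD replicate 2, 382.1 on HMM and 408.9 on DBM. Because the arrays differed by more than the 5% set beforehand, each was rescaled to the common trimmed mean. Signals were put on the log2 scale as log2(signal + 17.99), the offset being 0.25 times the median rescaled signal of 71.95. Fold changes are on this scale and understate the change of dim genes. Probe sets with a mean rescaled signal under 41.37, the 40th percentile, were left out, which left 19523 probe sets for testing, 10593 of them with 1 symbol, for 7989 gene symbols. The number of arrays limits the precision of every value.

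Differences were tested with limma 3.58.1 in R 4.3.3, by lmFit on a model with 1 mean for each injected RNA and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment at 0.05. The contrasts were ICD against the mean of DBM and HMM, ICD against DBM, and ICD against HMM. The fit has 1 residual degree of freedom, from the ICD arrays, and 5.82 prior degrees of freedom shared over probe sets, so the lone DBM and HMM arrays are assumed to vary like the ICD pair. DBM against HMM has 1 array on each side and is given as values without a test. Each of 19 gene lists with at least 5 genes tested was tested with camera at its preset correlation of 0.01. It used 1 probe set per gene, the one with the highest mean signal. With that preset a camera p-value weighs the list genes against all other genes, by the spread between genes. It gives no measure of the spread between embryos or arrays. For the difference of DBM from HMM, the median of a list was ranked among 10000 random lists of the same size matched on mean expression. That ranking, and the correlation of this difference with the difference between the ICD arrays, were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

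The contrasts and their tests, the 19 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule for named genes took, for ICD against the mean of DBM and HMM, the 12 highest and the 12 lowest named genes past the threshold with both ICD arrays on the same side of DBM and HMM. It further took up to 4 members of each list with the largest difference, any member past the threshold, any measured member of the Notch, multiciliate cell and ionocyte lists, and the 5 genes highest and lowest in DBM against HMM. Symbols starting with LOC, MGC or XB did not count as names, a choice made after the data had been opened. The genes of the closing section that fall outside the rule were chosen after their values were seen. As values added later, agr2.S, foxa1.S, foxi4.2.S, myc.S, otx2.S and the L copies of gata4, gata5, gata6, krt12.4, grhl3, cldn6.1 and prph are given. They are not among the named genes counted over the settings. The pipeline was tested on simulated data for the contrast of ICD with the mean of DBM and HMM, over 19523 probe sets. It recovered 99 of 100 probe sets changed by 3 on the log2 scale and 23 of 100 changed by 1, with 10 false calls among 132, and made 0 calls in data without change. The simulated arrays were independent and all had the spread of the ICD pair. They therefore give no error rate for the calls in the real arrays.

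The alternatives were quantile normalization, an offset of 1 times the median, no offset with signals floored at 1, no filter, a filter at the 60th percentile, eBayes without the trend and with robust settings, DBM and HMM as 1 group, each array left out, all probe sets of a gene, camera with an estimated correlation, and fry. Camera with an estimated correlation and the directional test of fry rest on the 1 residual degree of freedom, so they have little power. How often they would pass a changed list was not simulated. A fit with a block for arrays that resembled each other was also run, after the data had been seen. Its results were left out, because the block was read from the values under test.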

Results

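Animal caps of Xenopus laevis, the presumptive ectoderm that forms the mucociliary epidermis, were profiled after injection of embryos with RNA for ICD (2 arrays), DBM (1 array) or HMM (1 array). The series title places the experiment in a search for early targets of Notch signaling that bear on multiciliate cell fate. ICD is the usual name of the active intracellular domain of Notch, and DBM that of a DNA-binding mutant of its effector. No array of uninjected caps was among those analysed here, so every difference is between injected groups. ICD replicate 1 was dim, with a trimmed mean signal of 150.7 against 376.8 on ICD replicate 2, 382.1 on HMM and 408.9 on DBM. Its hybridization spike-ins were at 108% of the mean of the other arrays and its poly-A spike-ins at 32.0%. The ratio of 3' to 5' gapdh signal was 1.93 on that array, 1.30 on ICD replicate 2, 1.61 on HMM and 1.29 on DBM. Across the 19523 tested probe sets the ICD arrays correlated at r = 0.96 and DBM with HMM at r = 0.95. The remaining pairs gave 0.94 for ICD replicate 1 with HMM, 0.93 for ICD replicate 2 with DBM, 0.91 for ICD replicate 1 with DBM and 0.90 for ICD replicate 2 with HMM. Probe sets are not independent replicates.

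The main comparison asked which transcripts differed between caps with ICD and caps with DBM or HMM. Several hes5 genes, Hairy/Enhancer-of-split repressors that Notch activates directly, had some of the largest differences on the higher side. The probe set of hes5.2.L (Entrez Gene 398151) stood at a signal of 4324 ± 289 (SD, n = 2) with ICD against 9.23 with HMM and 27.2 with DBM, a log2 difference of 6.95 ± 0.24 (SE, adjusted p = 2.65e-04). The HMM and DBM signals lie under the filter level, so the size of this difference depends on the offset, and it ran from 5.61 to 8.09 over the settings. hey1.S (Entrez Gene 399195), a related repressor, stood at 6050 ± 22.6 (SD, n = 2) against 114 with HMM and 137 with DBM, a 42.4-fold difference. On the lower side, dll1.L, which encodes a ligand of Notch, stood at 128 ± 10.9 (SD, n = 2) with ICD against 5296 with HMM and 5341 with DBM, 36.7-fold apart (adjusted p = 3.15e-04). mcidas.S, the copy annotated for the coactivator that starts the multiciliate cell program, fell by 5.19 ± 0.36 (SE) on the log2 scale. Its ICD signal of 13.3 ± 11.1 (SD, n = 2) lies under the offset, and the difference ran from -6.66 to -3.77 over the settings. In all, 768 of 19523 probe sets passed the limma test at an adjusted p of 0.05, 370 higher and 398 lower with ICD, which covered 189 and 215 named genes. As with all arrays, the spread came from the 2 ICD arrays when DBM or HMM was left out. The contrast was then ICD against the remaining RNA alone, and the count was 337 without DBM and 427 without HMM. Those counts therefore largely repeat the comparisons of ICD with HMM and with DBM given below. Without an ICD array no spread is left unless DBM and HMM form 1 group, so those settings change both choices. That grouping alone gave 411, and then 150 without ICD replicate 1 and 62 without ICD replicate 2. In the counts below, values without an ICD array stand beside the value with DBM and HMM as 1 group.

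Of the 25 Notch pathway genes measured, 14 rose, 2 fell and 9 did not pass. Adjusted over the list alone, 15 were higher and 3 lower. Besides hes5.2.L and hey1.S, the highest values were those of hes5.1.L with a log2 difference of 5.92 ± 0.21 (SE), hes5.6.L with 5.36 ± 0.26, hes5.1.S with 5.21 ± 0.24, hes4.S with 4.78 ± 0.22 and hes5.5.S with 4.76 ± 0.29. The largest adjusted p of these was 8.20e-04, that of hes5.5.S. Their order depended on the setting, with hes5.6.L between 4.28 and 6.06 and hes5.1.S between 4.90 and 5.45. hes5.7.L, hes5.2.S, hes5.10.L and hes5.3.L rose by 3.59 to 4.11. nrarp.S, which encodes a feedback inhibitor of Notch, rose 9.26-fold from a high level, and jag1.L, a ligand gene, rose 3.45-fold. myc.L rose 3.26-fold, while its other copy myc.S did not pass (log2 difference 0.32, adjusted p = 0.837). hes1.L, another gene of the same repressor family, fell 9.47-fold (adjusted p = 2.15e-03), so the ligand gene dll1.L and hes1.L were the 2 members that went down. hes4.L (log2 difference 0.96, adjusted p = 0.107) and notch1.S (-0.35, adjusted p = 0.694) did not pass. The median of the list was 1.79 (camera, adjusted p = 2.62e-13; adjusted p = 0.364 with an estimated correlation), and 0.39 without the filter on dim probe sets and 3.21 with the filter at the 60th percentile. Of the 16 calls, 15 remained without DBM, 14 without HMM and 15 with DBM and HMM as 1 group, where 13 remained without ICD replicate 1 and 12 without ICD replicate 2.

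**Figure D1:**
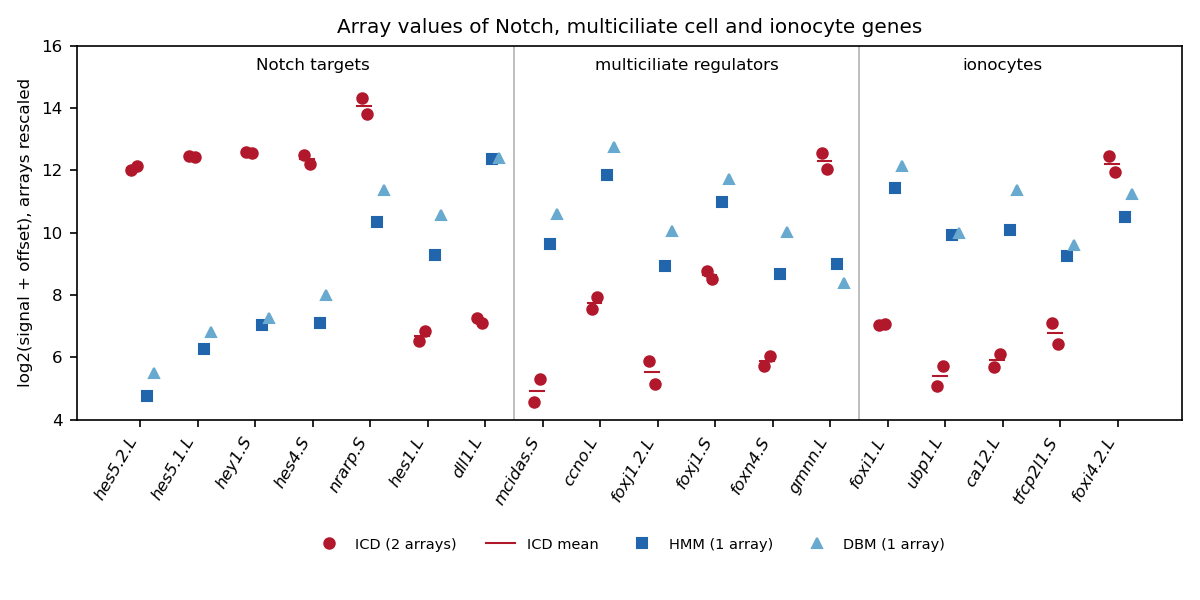
Each point is 1 array and gives the rescaled log2(signal + offset) of a gene's probe set, with a bar at the mean of the 2 ICD arrays; genes stand along the x axis by list. The ICD arrays of hey1.S lie at 12.57 and 12.56 against 7.05 with HMM and 7.28 with DBM, and those of mcidas.S at 4.55 and 5.29 against 9.63 and 10.59.

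Several regulators of the multiciliate cell program were lower with ICD. Of 16 measured, 8 fell, 2 rose and 6 did not pass, with the same numbers when adjusted over the list alone. Besides mcidas.S, these were ccno.L (-4.55 ± 0.23 SE) and ccno.S (-3.96 ± 0.27), copies of a cyclin gene needed for centriole amplification, foxn4.S (-3.46 ± 0.30), rfx2.S (-1.41 ± 0.28), both copies of foxj1, the regulator of motile ciliogenesis, foxj1.S (-2.72 ± 0.22) and foxj1.L (-1.30 ± 0.23), and its paralog foxj1.2.L (-3.98 ± 0.36). The 2 that rose were both copies of geminin, a replication inhibitor related to mcidas: gmnn.L (3.59 ± 0.25) and gmnn.S (3.22 ± 0.22). e2f4.S (0.30, adjusted p = 0.768) and mybl2.S (0.42, adjusted p = 0.526) did not pass. The median of the list was -0.75 (camera, adjusted p = 8.77e-03; adjusted p = 0.385 with an estimated correlation), and -1.30 with the filter at the 60th percentile and -0.20 with all probe sets of a gene. Of the 10 calls, ccno.L, mcidas.S and both geminin copies were kept with each array left out in turn.

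Some structural genes of cilia and centrioles were lower with ICD as well. Of 43 motile cilia genes 21 fell, 0 rose and 22 did not pass (38 and 0 adjusted over the list alone), among them cfap52.S (-3.67 ± 0.31 SE), the tektins tekt2.S (-3.14 ± 0.32) and tekt4.S (-2.92 ± 0.29), the radial spoke gene rsph1.L (-2.68 ± 0.30), the tubulin gene tubb4b.S (-2.45 ± 0.23) and the dynein gene dnai1.L (-1.61 ± 0.28). The median of the list was -1.35 (camera, adjusted p = 1.10e-26; adjusted p = 0.364 with an estimated correlation). Of 25 centriole genes 7 fell, 0 rose and 18 did not pass, and 12 fell when adjusted over the list alone. They included cetn4.L (-2.74 ± 0.24), poc1a.L (-1.89 ± 0.21), cep152.L (-1.72 ± 0.27) and stil.L (-1.27 ± 0.25), with a list median of -0.82 (camera, adjusted p = 2.91e-08; adjusted p = 0.364 with an estimated correlation). Of 27 genes of intraflagellar transport and the basal body 3 fell, cep83.L, ift52.L and arl3.S, and 24 did not pass, with 5 lower when adjusted over the list alone. That list's median was -0.65 (camera, adjusted p = 1.09e-08; adjusted p = 0.364 with an estimated correlation). Of the 21 motile cilia calls 20 remained without HMM, 5 without DBM and 6 with DBM and HMM as 1 group, where 1 remained without ICD replicate 1 and 0 without ICD replicate 2. In the same order the 7 centriole calls gave 4, 1, 3, 0 and 0, and the 3 calls of intraflagellar transport and the basal body 1, 0, 0, 0 and 0.

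Ionocytes are the proton- and ion-transporting cells that arise beside multiciliate cells in this tissue. Of 29 genes of their list 8 fell, 2 rose and 19 did not pass, and adjusted over the list alone 10 were lower and 2 higher. ca12.L, a carbonic anhydrase gene, fell 28.3-fold, and foxi1.L (Entrez Gene 380059), the regulator that specifies ionocytes, went from 2736 with HMM and 4523 with DBM to 114 ± 2.70 (SD, n = 2) with ICD, a 26.8-fold difference (adjusted p = 3.78e-04). ubp1.L fell 23.4-fold. gadd45g.L, tfcp2l1.S and the proton pump subunit genes atp6v1g3.L and atp6v1b1.L fell by 3.64, 2.65, 2.36 and 1.77 on the log2 scale. tfcp2l1.L had a value of -1.09 (adjusted p = 0.125). The 2 that rose were foxi4.2.L (1.33 ± 0.26 SE), a forkhead gene of the early ectoderm, and atp6v1f.L (1.38 ± 0.22), a proton pump subunit gene. The other copy foxi4.2.S did not pass (-0.18). The median of the list was -0.41 (camera, adjusted p = 8.49e-05; adjusted p = 0.364 with an estimated correlation). Of the 10 calls foxi1.L, ca12.L, ubp1.L and gadd45g.L were kept with each array left out in turn.

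Proneural and neuronal genes went both ways, with 6 of 16 lower and 1 higher (7 and 4 adjusted over the list alone). Besides dll1.L and the gadd45g copies, the Delta-type ligand gene dlc.L fell by 4.59 on the log2 scale. The zinc finger genes insm1.L and myt1.S fell 3.63-fold and 3.04-fold. prph.S, which encodes the intermediate filament peripherin, rose 9.56-fold, while its other copy prph.L did not pass over all probe sets (log2 difference 0.94). The list as a whole had an adjusted p of 0.0665 by camera, which became 3.10e-03 without HMM. The goblet and outer epidermal layer list had 3 higher and 4 lower of 27, in the same numbers over the list alone (median 0.00, camera adjusted p = 0.819). itln1.L, the intelectin of goblet cells, fell 10.7-fold, and krt12.4.S, grhl3.S and ppl.L fell by 1.35 to 1.44 on the log2 scale. The other copies krt12.4.L (-0.15) and grhl3.L (-0.68) did not pass. krt19.L and krt19.S rose 5.84-fold and 5.55-fold, and cldn6.1.S rose 2.24-fold, while its other copy cldn6.1.L did not pass (log2 difference 0.64). Among 6 genes of small secretory cells foxa2.L rose 13.8-fold and agr2.L fell 2.75-fold, with 2 higher and 2 lower over the list alone (camera, adjusted p = 0.571). The other copy agr2.S (log2 difference 0.96, limma adjusted p = 0.0954) and foxa1.S (-1.41, adjusted p = 0.136) had the opposite signs and did not pass over all probe sets. Of the 7 proneural calls 3 remained without DBM, 5 without HMM and 4 with DBM and HMM as 1 group, where 4 remained without ICD replicate 1 and 3 without ICD replicate 2. The same order gave 3, 4, 4, 2 and 0 for the 7 goblet and outer layer calls and 1, 2, 1, 1 and 0 for the 2 small secretory calls.

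**Figure D2:**
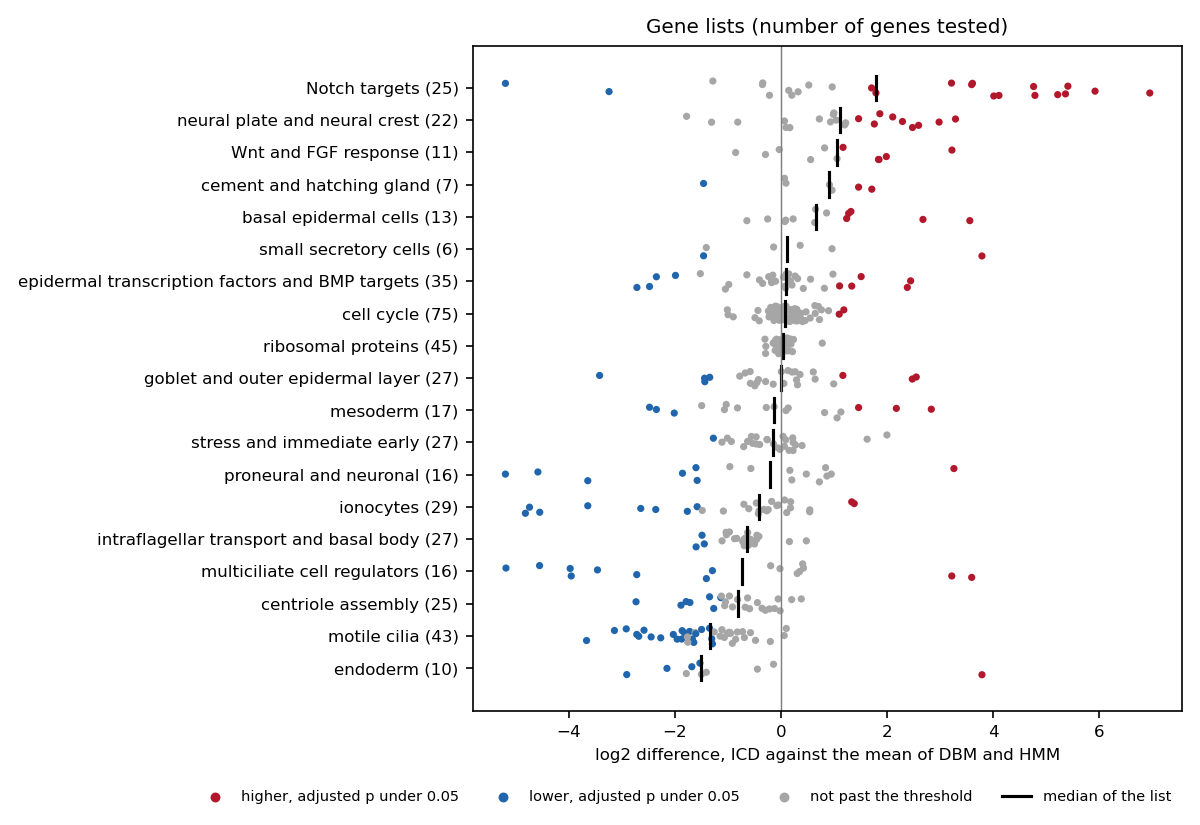
The log2 difference of ICD from the mean of DBM and HMM (x axis) for each tested gene of the 19 lists (y axis, with the number of genes), coloured by the limma test. The black bar is the list's median, from 1.79 for Notch targets to -1.35 for motile cilia and -1.52 for endoderm.

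Of 13 markers of basal epidermal cells 5 rose, 0 fell and 8 did not pass (6 higher and 1 lower over the list alone). They were sox11.S (3.56 ± 0.25 SE), the epidermal stem cell regulator tp63.S (2.67 ± 0.33), vim.L (1.32 ± 0.21), fgfr2.L (1.27 ± 0.22) and nectin2.L (1.23 ± 0.22), with a list median of 0.65 (camera, adjusted p = 2.56e-05; adjusted p = 0.364 with an estimated correlation). Of the neural plate and neural crest genes 9 of 22 rose and 0 fell (12 higher and 2 lower over the list alone), including the transcription factor genes sox9.S (3.29 ± 0.30), irx1.L (2.98 ± 0.29), zic1.S (2.59 ± 0.26), sox3.S (2.48 ± 0.29) and sox8.L (2.29 ± 0.25). Their median was 1.12 (camera, adjusted p = 1.88e-09; adjusted p = 0.364 with an estimated correlation). Genes that respond to Wnt or FGF signals gave 5 of 11 higher and 0 lower (5 and 0 over the list alone), among them the Wnt receptor gene fzd7.L (9.32-fold), the secreted Wnt modulator gene sfrp2.S (3.95-fold), the feedback gene axin2.L (3.59-fold), sp5.L (3.57-fold) and the FGF-responsive etv4.L (2.25-fold). The median was 1.05 (camera, adjusted p = 3.47e-05; adjusted p = 0.406 with an estimated correlation). Without the filter on dim probe sets the neural median was 0.44 and the Wnt and FGF median 0.35. The Wnt and FGF median was also 0.64 with an offset of 1 times the median signal, 0.69 without HMM and, with DBM and HMM as 1 group, 0.61 without ICD replicate 2. It rose to 1.84 with the filter at the 60th percentile and to 1.35 without DBM. Of the 5 basal calls 3 remained without DBM, 2 without HMM and 4 with DBM and HMM as 1 group, where 1 remained without ICD replicate 1 and 0 without ICD replicate 2. The same order gave 7, 5, 6, 4 and 1 for the 9 neural calls and 3, 1, 1, 1 and 0 for the 5 Wnt and FGF calls.

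Of 10 endoderm genes 4 fell and 1 rose (7 and 1 over the list alone; median -1.52, camera adjusted p = 1.40e-04; adjusted p = 0.364 with an estimated correlation). gata6.S, gata5.S and gata4.S, GATA factors of endoderm and heart precursors, fell 7.52-fold, 2.89-fold and 3.21-fold, hhex.L fell 4.45-fold, and foxa2.L was the member that rose. The other GATA copies did not pass over all probe sets, at -1.50 for gata6.L, -0.14 for gata5.L and -1.79 for gata4.L on the log2 scale. Without the filter on dim probe sets the endoderm median was -0.16. Mesoderm genes gave 3 higher and 3 lower of 17, with not.L and fgf3.L up 7.12-fold and 4.51-fold and wnt11b.L down 4.04-fold (4 and 4 over the list alone; camera, adjusted p = 0.998). Epidermal transcription factors and BMP targets gave 5 higher, among them dlx6.L (2.44 on the log2 scale), klf17.L (2.38), dlx6.S (1.51) and dlx5.L (2.15-fold), and 4 lower, klf2.S (-2.72), szl.L (-2.48), szl.S (-2.35) and msx2.L (-1.99), of 35 (6 and 7 over the list alone; median 0.08 and mean -0.06, camera adjusted p = 0.571). In the cement and hatching gland list ag1.L and otx2.L rose and agr2.L fell, of 7 genes, with 4 higher and 1 lower over the list alone. The other copies agr2.S (0.96) and otx2.S (0.09) did not pass over all probe sets. The median was 0.91 (camera, adjusted p = 0.0141, and 0.387 with an estimated correlation). It was 0.47 without the filter on dim probe sets and 0.42 without HMM, where the list did not pass. With DBM and HMM as 1 group it was 0.57 without ICD replicate 2. The cell cycle list shifted by a median of 0.07, with 2 of 75 genes higher, the replication licensing genes cdc6.L and cdt1.L, and 0 of 75 over the list alone. Its camera adjusted p of 0.0187 became 0.385 with an estimated correlation. The list did not pass without DBM (median 0.06) or, with DBM and HMM as 1 group, without ICD replicate 2 (0.11). It still passed without HMM, where its median was 0.21. Of 27 stress and immediate early genes 1 passed, btg2.S, which fell 2.42-fold (1 over the list alone; camera, adjusted p = 0.253). Of 45 ribosomal protein genes 0 passed in either count, and 0 over the list alone (median 0.03, camera adjusted p = 0.492). With DBM and HMM as 1 group that list's median was -0.20 without ICD replicate 1 (camera, adjusted p = 3.50e-03) and 0.27 without ICD replicate 2 (adjusted p = 1.63e-06), so its direction depended on the ICD array used. Of the 5 endoderm calls 2 remained without DBM, 3 without HMM and 3 with DBM and HMM as 1 group, where 2 remained without ICD replicate 1 and 0 without ICD replicate 2. The same order gave 3, 2, 3, 2 and 0 for the 6 mesoderm calls, 4, 3, 5, 3 and 1 for the 9 calls of epidermal transcription factors and BMP targets, and 1, 1, 0, 0 and 0 for the 3 gland calls. The cell cycle genes cdc6.L and cdt1.L lost their calls in each of these settings, and btg2.S kept its call only without HMM.

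The remaining genes of the 12 highest were cnfn.1.L (4.50 ± 0.31 SE), ptn.L (4.26 ± 0.21), which encodes the heparin-binding growth factor pleiotrophin, and enc1.2.S (4.08 ± 0.31). Among the 12 lowest were both copies of the receptor tyrosine kinase gene kit, kit.L (-4.42 ± 0.38) and kit.S (-4.16 ± 0.25), together with val.L (-4.40 ± 0.26) and tsga10.L (-4.21 ± 0.28). Of 9 settings, cnfn.1.L, enc1.2.S and val.L passed in all, tsga10.L in 8, and ptn.L, kit.L and kit.S in 7. The value of kit.L ran from -6.15 to -3.01. A count that needs no estimate of the spread gave 762 probe sets at least 2-fold apart in all 4 pairings of an ICD array with DBM or HMM, 359 higher and 403 lower with ICD. The other ways to split the 4 arrays gave 327 for ICD replicate 1 and HMM against ICD replicate 2 and DBM, and 2 for ICD replicate 1 and DBM against the others. With an array left out the count, which then needs fewer pairings, lay between 1094 and 1279.

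The next comparisons asked whether ICD differed from DBM and from HMM alike. Against DBM 452 probe sets passed, 164 higher and 288 lower with ICD, and against HMM 340 passed, 241 higher and 99 lower. The Notch targets hes5.2.L, hes5.1.L and hey1.S rose and dll1.L, foxi1.L, ccno.L and mcidas.S fell in both. The comparisons shared 232 calls, 144 higher and 88 lower, and 0 were opposite. Independent calls would share 2.02 higher and 1.46 lower. The same ICD arrays and spread enter both comparisons, so that value is no fair measure of the overlap without change. Across probe sets, the difference of ICD from DBM correlated with that from HMM at r = 0.66 (covariance 0.31), while unchanged groups simulated against the same ICD arrays gave r = 0.33 (covariance 0.05). The simulated arrays were drawn independently, which leaves out the grouping of ICD replicate 1 with HMM and of ICD replicate 2 with DBM. Their value is therefore no full measure of the correlation without change. Part of the overlap and the correlation may come from the shared ICD arrays. With no array in common the value depended on the pairing, at r = 0.22 for ICD replicate 1 over DBM with ICD replicate 2 over HMM and r = 0.76 for ICD replicate 2 over DBM with ICD replicate 1 over HMM. Without the filter on dim probe sets the counts were 220 against DBM and 224 against HMM, and without the intensity trend 223 and 170.

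DBM and HMM were set side by side as values, since each had 1 array and the difference has no replicate check. Of the probe sets, 1317 were at least 2-fold apart, 754 higher and 563 lower with DBM, against 1095 between the ICD arrays. The comparison of gene lists below was added after the data had been seen. Most of the chosen lists shifted: 17 of the 19 had a median above 0 for DBM over HMM. At percentile 100 among random lists lay 11, among them mesoderm (0.65), Wnt and FGF response (0.73), cement and hatching gland (0.69), neural plate and neural crest (0.42) and goblet and outer layer (0.35). Over all tested probe sets the median of ICD over DBM was 0.02 and that of ICD over HMM -0.05. These medians show no shift of the typical probe set toward DBM. The motile cilia genes stood higher with DBM in 42 of 43 cases, with a median log2 difference of 0.94 (percentile 100 among 10000 random lists), against 0.12 between ICD replicate 2 and ICD replicate 1. The Notch targets were higher with DBM in 22 of 25 cases (median 0.33, percentile 100). The multiciliate regulators had a median of 0.50 (percentile 100) and the ionocyte genes one of 0.15 (percentile 98.7). Between ICD replicate 2 and ICD replicate 1 the medians were 0.52 for mesoderm, 0.31 for Wnt and FGF response, 0.26 for neural plate and neural crest and 0.25 for multiciliate regulators. Those of cement and hatching gland (-0.04), goblet and outer layer (-0.07), Notch targets (-0.04) and ionocytes (-0.07) lay below 0. Ribosomal protein genes were lower with DBM in the median (-0.18, percentile 0.0) and lower on ICD replicate 2 than on ICD replicate 1 (-0.46, percentile 0.0). The 5 named genes highest with DBM were rnf222.S (2.92), cldn1.S (2.82), cd81.L (2.70), slc25a24.L (2.31) and bet1l.S (2.27) on the log2 scale. The 5 lowest were gpr160.S (-3.67), cdh1.S (-3.53), acp1.L (-3.40), cry4.L (-3.18) and gng7.S (-3.05). These genes differed in the same direction between ICD replicate 2 and ICD replicate 1, by 0.63 for cldn1.S, by 1.65 to 3.69 for the others higher with DBM and by -4.55 to -2.71 for those lower. Over all tested probe sets the difference of DBM from HMM correlated with that of ICD replicate 2 from ICD replicate 1 at r = 0.64, so a difference between DBM and HMM also ran along a difference between the ICD replicates.

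**Figure D3:**
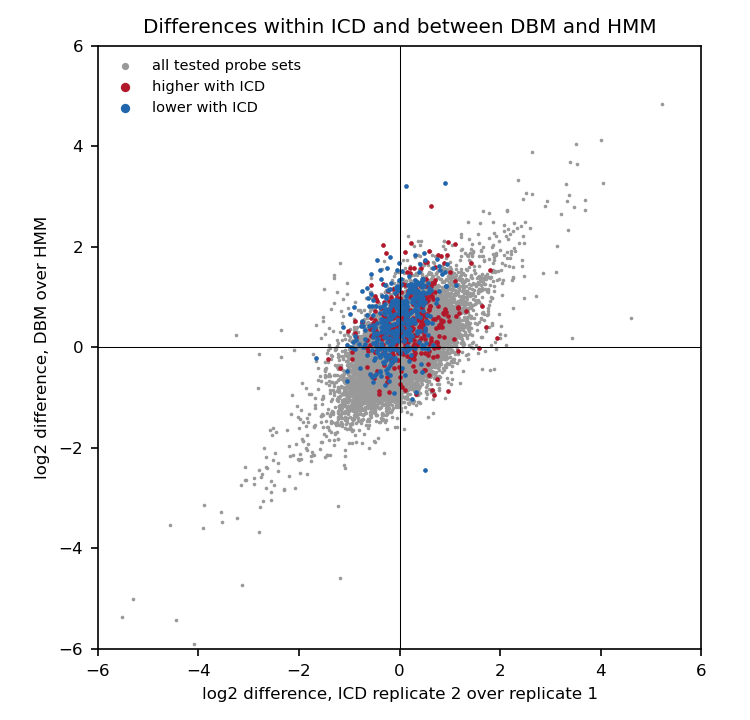
Each point is 1 of 19523 probe sets, with the log2 difference of ICD replicate 2 from ICD replicate 1 on the x axis and that of DBM from HMM on the y axis, and with the probe sets called higher or lower with ICD in colour. The cloud runs along the diagonal (r = 0.64).

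The RNA of the Notch effector itself was read by 3 probe sets of rbpj.S. The DBM array was 9.63-fold above the mean of the other 3 arrays in 1 of them, at a log2 value of 11.81 against 8.46 and 8.58 with ICD and 8.60 with HMM. The other probe sets of rbpj.S differed by 0.34 and -0.32 on the log2 scale. In ICD against the mean of DBM and HMM that probe set passed (-1.69, adjusted p = 0.0102), through the DBM array alone, with a difference of -0.08 from HMM (adjusted p = 0.952). The brightest rbpj.S probe set did not pass (-0.22, adjusted p = 0.814). notch1.S stood 0.55 above the other arrays with DBM.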

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

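All of the tests in this part were chosen after the result they weigh was seen, and for the probe set test single genes whose probe sets disagreed had been noticed before its median was computed. The small secretory cell list stood out because the median of its differences placed each ICD array below DBM and above HMM. Its median was 1.04 for DBM over HMM, against -0.13 for ICD over DBM and 0.35 for ICD over HMM. Between ICD replicate 2 and ICD replicate 1 it was 0.50 (percentile 99.4 among random lists), so part of the difference also ran between the ICD arrays. The list has 6 genes and each side 1 array, and the difference was not tested.

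The arrays also grouped across the injected RNAs: 327 probe sets separated ICD replicate 1 and HMM from ICD replicate 2 and DBM by at least 2-fold. The low brightness of ICD replicate 1 cannot by itself give the part of this between DBM and HMM, which holds neither ICD array. Over all tested probe sets that difference followed the one of ICD replicate 2 from ICD replicate 1 with r = 0.64. This correlation largely restates the grouping and is no independent test of it. In the 65 genes with further probe sets, those showed a median share of 0.0645 of the difference (95% bootstrap interval -0.000337 to 0.155), against 0.719 in the 101 such genes of the ICD comparison. Such a low share could come from sequence variants under single probe sets, but the labels name no clutch or batch, and selecting each gene by its most extreme probe set lowers the share in both comparisons. RNA quality was not tested and stays open: the ratio of 3' to 5' gapdh split the arrays the same way (1.93 on ICD replicate 1 and 1.61 on HMM against 1.30 on ICD replicate 2 and 1.29 on DBM), while that of 3' to middle actin did not (2.02 and 1.38 against 1.38 and 1.46).

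The DBM array was high in 1 probe set of rbpj.S. A higher level of the endogenous RNA would raise the other rbpj.S probe sets, of which the highest stood at 0.344 on the log2 scale, against 3.27 for the probe set in question. Its excess over every other array ranked 2 among all tested probe sets, which might reflect injected RNA that holds rbpj sequence. The labels do not give the sequence of the injected RNA, so this stays open.

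The motile cilia genes stood higher with DBM than with HMM, as did most lists. A shift acting alike with and without ICD is argued against by the median of 0.760 left after subtracting the difference of the ICD arrays. In the 37 genes over the filter in the ICD arrays that median was 0.702, with 35 of them above 0. These medians cannot weigh against a difference between arrays that acts less where ICD lowers the genes, since it would leave a remainder too. A stronger block of Notch by DBM is argued against by the Notch targets raised by ICD, of which 12 of 14 were higher with DBM, though the shift of most lists toward DBM lowers the weight of that count. Further development of the explants on the DBM array could also give the median of 0.943, and with 1 array each the design cannot tell. No other biological explanation was tested.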

How the results depend on the processing

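The alternatives of this part were chosen before the data were seen, apart from the named genes with DBM and HMM as 1 group, added later, and a fit with a block read from the correlation of the arrays, which was run after seeing the data and is not reported because the block came from the values under test. For ICD against the mean of DBM and HMM the 768 calls became 337 without DBM, 427 without HMM and 411 with DBM and HMM as 1 group. Leaving out an ICD array needs that grouping, so its baseline is 411, which became 150 without ICD replicate 1 and 62 without ICD replicate 2. The share of calls that were higher with ICD was 74.5% without DBM and 38.9% without HMM, against 48.2% with all arrays. Leaving out DBM or HMM turns the contrast into ICD against the remaining RNA alone. The 452 calls against DBM became 220 without the filter and 223 without the trend, and the 340 against HMM became 224 and 170. Between DBM and HMM the count of 1317 became 622 with an offset of 1 times the median and 793 with the filter at the 60th percentile. The count of 762 in all 4 pairs became 480 with that offset and 1094 to 1279 with an array left out, where fewer pairs have to pass by construction. The correlation of 0.664 became 0.675 with the larger offset, 0.656 without an offset, 0.628 without the filter and 0.703 at the 60th percentile. By camera 12 of the 19 lists passed, 11 to 14 with an array left out, and 0 with an estimated correlation or by the directional test of fry. Those 2 tests rest on 1 residual degree of freedom and have little power, so a list that failed them may still differ. The test of fry for change in either direction did pass lists. Its adjusted p was 0.0405 for Notch targets and ionocytes and 0.0472 for multiciliate regulators and motile cilia. It was also 0.0405 for mesoderm, which did not pass by camera, and 0.914 for ribosomal proteins. By construction the medians do not depend on the set test. They were 1.79 for Notch targets, -0.75 for multiciliate regulators, -1.35 for motile cilia and -0.41 for ionocytes. With an estimated correlation their camera adjusted p was 0.364, 0.385, 0.364 and 0.364 in that order. With the directional test of fry the adjusted p was 0.0915 for Notch targets and 0.102 for the other 3. With an array left out the medians ran from 1.53 to 2.34, from -0.91 to -0.56, from -1.91 to -0.91 and from -0.42 to -0.38. The filter, which changes the members by construction, moved all but that of motile cilia further: without it the medians were 0.39, -0.53, -1.13 and -0.26, and at the 60th percentile 3.21, -1.30, -1.61 and -0.33. With all probe sets they were 1.66, -0.20, -1.33 and -0.28. The ribosomal protein list went from 0.03 to -0.20 without ICD replicate 1 (camera, adjusted p = 3.50e-03), and was 0.27 without ICD replicate 2 (1.63e-06). The proneural list passed with the 60th percentile filter (0.0436), with all probe sets (8.13e-03), without HMM (3.10e-03), without ICD replicate 1 (0.0477) and without ICD replicate 2 (0.0181). The cause of these moves was not tested. Of 117 genes named in the text for ICD against the mean, 75 kept their call status without DBM, 85 without HMM and 80 with DBM and HMM as 1 group, where 52 kept it without ICD replicate 1 and 33 without ICD replicate 2, and 0 reversed. No paired analysis was possible because the groups share only replicate number 1 in the labels, and the block named above was no pairing given by the design. MAS5 signals limit what can be said of dim probe sets, whose folds depend on the offset.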

Other observations

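The genes of this part were chosen after their values were seen. Single genes are given and no group was tested. prdm1.S, a zinc finger gene of the neural plate border, rose in each of its 3 probe sets, by 2.90 to 3.61 on the log2 scale (limma, adjusted p = 1.52e-03 for the largest). pax7.L, a paired box gene of border and neural crest, rose by 2.90 (adjusted p = 8.97e-03) and otx1.L, a homeobox gene of the head, rose by 2.95 (adjusted p = 8.81e-03).

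On the lower side were sox7.L, which acts in endoderm and vessels, with -3.91 (limma, adjusted p = 1.95e-03), the chemokine receptor gene cxcr4.S with -3.42 (adjusted p = 1.55e-03) and hand2.S, a gene of lateral mesoderm, with -2.84 (adjusted p = 7.23e-03). hmx2.S and pou2f3.L, regulators of sensory and chemosensory cells, fell by 1.84 (adjusted p = 0.0313) and 1.77 (adjusted p = 0.0421). cldn1.S, a tight junction gene, was higher with ICD by 3.59 (adjusted p = 1.85e-03) and also stood 2.82 higher with DBM than with HMM, the latter on 1 array each. With an array left out, or with DBM and HMM as 1 group, only cxcr4.S kept its call throughout; the largest adjusted p was 0.240 for hmx2.S, 0.173 for pou2f3.L and 0.325 for cldn1.S. These genes were picked from all calls, so they give no measure of how common such genes are, and no explanation was tested.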
